A study of Schizosaccharomyces pombe with 12 samples.

How the data were processed

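The material was genomic DNA of the fission yeast Schizosaccharomyces pombe from 2 strains, cdc25-22 and cdc25-22 rad3∆. The cdc25-22 mutation makes the phosphatase Cdc25, which drives entry into mitosis, fail at high temperature. The gene rad3 encodes the ATR-like kinase of the DNA replication and damage checkpoint. Per the labels' protocols, cells were blocked for 4 h at 36.5 °C and released at 25 °C. Hydroxyurea, which lowers the supply of deoxyribonucleotides and slows replication forks, was added to 6 mM at 5 min after release. Unreplicated DNA was sampled at that point, and S phase DNA after a time at which S phase would have been over without the drug. Each array set S phase DNA of a strain against unreplicated DNA of the same strain. The labels give 3 replicates per strain, each with 2 arrays of opposite dye order, or 12 arrays in all. Both arrays of a replicate carried the same pair of DNA samples and counted as 1 replicate (n = 3 per strain). The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

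The deposited values are spot intensities of 2-colour Agilent arrays, with processed signals and with median signals of spot and local background per channel. Per the file headers, the processed intensities were background-subtracted, spatially detrended and dye-normalized with linear factors by the scanner software, and no lowess step was applied. Those factors lay between 0.115 and 0.489 for green and between 0.141 and 0.572 for red. The headers name Agilent Feature Extraction 10.7.1.1, whereas the submitters' processing notes name 10.7.3.1. Replicates 1 and 2 were extracted with a protocol for comparative genomic hybridisation and replicate 3 with one for chromatin immunoprecipitation, per the file headers. The replicates of both strains with the same number lay on 1 slide, so slide and replicate number are the same split. The extraction protocol sets only replicate 3 apart from replicates 1 and 2. The values of 1 array were deposited with 3 significant digits.

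Each array held 42707 genomic probes, of which 42641 were nuclear and 66 mitochondrial, and 2513 control spots. The median over probes of the unprocessed spot signals ran per array from 2585 to 10250 in green and from 1982 to 8628 in red, against local backgrounds of 47 to 121 and 50 to 98. Between 97.2% and 100.0% of probes per array were well above background, and 41460 probes were so in both channels on every array. For arrays such as these the number of arrays limits the precision.

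Control spots and spots marked as outliers by the scanner software (13 to 1036 probes per array) were left out. The log2 ratio of S phase over unreplicated DNA was taken from the processed signals, turned the same way on every array, and centred on each array's median over nuclear probes. Array profiles were averaged over the dye pair. Probe values were averaged in windows 3 kb wide at steps of 1 kb with at least 3 probes, which gave 12161 windows with a median of 11 probes. A ratio of this kind gives replication of a place relative to the array's median, not the amount of DNA made.

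Windows were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), all 6 replicates in 1 model with a mean per strain and a shared spread. Each strain mean was tested against 0 and the strains against each other, with Benjamini-Hochberg adjustment over all windows and a threshold of 0.05. Origins were local maxima, within 5 kb on each side, of the profile averaged over both strains with equal weight. An origin was called in a strain where the adjusted p was under 0.05 and the strain mean was 0.2 or more. The strain difference was adjusted over the called origins alone and, beside it, over all windows. Lists of regions were tested with limma's fry, whose p tests whether the windows of a list move one way on balance, and with exact 2-sided permutation tests of 3 against 3 replicate means, whose smallest p is 0.1. Lists were the centromeres, the last 100 kb of both ends of chromosomes I and II (subtelomeres), the last 50 kb of chromosome III, the mating-type region, retrotransposons, tRNA, histone, MBF target and checkpoint genes, intergenic regions by orientation, the most AT-rich 5% of windows, mitochondrial probes, and the loci of ura4 and hus5. A gene stood for the window over its midpoint. The tests, lists and the rule for named genes were fixed before the data were examined.

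The rule named, in each strain, the 6 called origins with the largest mean. For the strain difference it named up to 6 origins each way with the largest difference past the threshold over the list alone, given that all 3 rad3∆ replicates lay on one side of all 3 cdc25-22 replicates. It also named rad3, cdc25, ura4, hus5 and members of the histone, MBF and checkpoint lists.

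Coordinates are those of the files, whose headers tag an older assembly than the reference used here, ASM294v3. To see where the reference could be used, the GC content of the reference at probe positions was correlated with the brightness of the probes in segments of 200 probes, at shifts of up to 8 kb. On chromosome I left of the centromere, on II and on III all of the 64, 77 and 42 segments were in step, with median best shifts of -6 bp. Right of the centromere of chromosome I, 30 of 31 segments were out of step by a median of 6147 bp. No gene is named there, and 10411 windows carry annotation from ASM294v3. Of 13 Tf2 retrotransposons, 0 had a window. Windows covered 125 of 171 tRNA genes, 7 of 10 histone genes, 10 of 12 MBF targets and 8 of 13 checkpoint genes.

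On simulated data with 200 planted origins and noise from the real replicates, the windows gave 66 of 67 origins of height 0.3 and all 67 of height 0.4. Of planted strain differences among called origins, 44 of 50 of 0.15 and 49 of 50 of 0.30 were found, and 1 of 99 unchanged origins was called changed. Planted heights were 0.3, 0.4 and 0.6, whereas the origins that rose in the real data had a median of 0.10 in cdc25-22. The planted cases also held no strain difference over broad regions. These rates therefore do not describe calls at weaker origins or within broad shifts.

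Alternatives were normexp background correction (offset 50) and plain background subtraction, both on median signals because mean signals were not used here, loess within arrays, centring on the mode or the 25th percentile, filters on dim, saturated and repeated probes, windows 1 or 5 kb wide, each dye order alone, a block for the replicate number or slide, each strain fitted alone, scaling by the profile SD, a GC correction, other thresholds for origins and leaving out each replicate. Alternatives chosen after seeing the data were the GC correction with the replicate block, leaving out loci of sharp spikes and the rad3 deletion, leaving out the right arm of chromosome I, and keeping rad3∆ replicate 1 alone. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were also used.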

Results

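DNA replication was profiled in 2 strains of fission yeast held in hydroxyurea after a synchronous release from a block in G2. Each strain, cdc25-22 and cdc25-22 rad3∆, had 3 replicates, and each replicate had 2 arrays of opposite dye order that set S phase DNA against unreplicated DNA. Values are log2 ratios centred on the array median, so a value above 0 marks DNA that was copied more than the median place on the array. Profiles of cdc25-22 replicates correlated with each other at r = 0.955 to 0.969 across windows, and those of rad3∆ replicates at 0.738 to 0.873. Replicates of different strains correlated at 0.806 to 0.909, so rad3∆ replicates were no more alike than replicates of different strains. Windows are not independent replicates.

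The labels were checked first on the deleted gene. In rad3∆ the 24 probes between 904607 and 911114 of chromosome II, inside the rad3 coding region (904365 to 911525), changed in brightness by a mean of -7.65 log2 units against cdc25-22. Across the 12 channels of the 6 rad3∆ arrays this change ran from -9.48 to -6.07, and across the 12 channels of the cdc25-22 arrays it ran from -0.40 to 0.19. Probes of deleted DNA have no target on the rad3∆ arrays, so the size of their fall reflects the floor of the signal. For 8 probes of the annotated rad3 transcript beyond that span the mean change was 0.11, and the 12 probes of cdc25 one of -0.02. Every array matched the strain on its label, while the dye order and the replicate number were not checked this way.

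The first comparison asked where origins fired in each strain under hydroxyurea. In cdc25-22 the highest origin with a gene name lay on chromosome III at 1067000 to 1069999, between chk1, which encodes a checkpoint kinase, and ppc1. Its log2 ratio was 0.49 ± 0.09 (SD, n = 3). Next on the same chromosome were origins in SPCC622.07 at 1408000 to 1410999 with 0.47 ± 0.06, in gst1 at 1718000 to 1720999 with 0.46 ± 0.02, between tef3 and SPCC417.09C at 1689000 to 1691999 with 0.45 ± 0.06, and in omh3 at 1608000 to 1610999 with 0.44 ± 0.02. The gene tef3 encodes a translation elongation factor. Above all of these stood a window at 3989000 to 3991999 of chromosome I with 0.52 ± 0.10, which rested on 3 probes and lies where no annotation could be used.

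In rad3∆ the origin in SPCC622.07 had 0.43 ± 0.04, the one between rpp202 and mat3-Mi at 2130000 to 2132999 of chromosome II had 0.42 ± 0.11, and the one in omh3 had 0.41 ± 0.11. The origin in ptl3 at 1079000 to 1081999 of chromosome I had 0.41 ± 0.05, and the unannotated window at 3989000 of chromosome I had 0.42 ± 0.08. The highest mean in rad3∆, 0.57 ± 0.48, belonged to a window in fib1, the gene of the nucleolar protein fibrillarin, at 2982000 to 2984999 of chromosome II. It rested on replicate 3 with 1.098, beside 0.17 and 0.44, and without that replicate the mean was 0.31 with an adjusted p of 0.0913 in limma. Replicate 3 of cdc25-22, on the same slide, was high there too, with 0.80 beside 0.10 and 0.14. None of these high origins of either strain passed the test of a strain difference, with adjusted p of 0.171 to 0.703 over the called origins alone. With the slide as a block the difference at fib1 passed (0.225, adjusted p = 0.0487 over all windows, with 0.0487 to 0.917 over all alternatives), and without rad3∆ replicate 3 it was -0.04. With replicate 1 of rad3∆ alone, a setting chosen after seeing the data, the difference at gst1 passed (-0.143, adjusted p = 0.0437).

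Origins that were mapped long before arrays were among the high places. The window over hus5, next to the long known origin ars1, had 0.37 ± 0.00 in cdc25-22 and 0.37 ± 0.04 in rad3∆. The 21 windows around ura4 on chromosome III, which hold a cluster of known origins, averaged 0.32 ± 0.04 in cdc25-22 and 0.25 ± 0.02 in rad3∆, and all 21 were above 0 in both strains. The centromeres averaged 0.31 ± 0.04 and 0.25 ± 0.03, with all 22 windows above 0 in both. All 3 lists lay above 0 in each strain by limma's fry, with adjusted p of 0.000197 in cdc25-22 and 0.000251 in rad3∆.

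In all, 176 origins were called in cdc25-22 and 236 in rad3∆ among 555 maxima, of which 165 were called in both strains. Called origins had a median log2 ratio of 0.32 in cdc25-22 and 0.30 in rad3∆, or 1.25-fold and 1.23-fold over the array median. The median distance between neighbours was 37 kb and 39 kb. Of the 176 in cdc25-22, chromosomes I, II and III held 58, 52 and 66, and of the 236 in rad3∆ they held 94, 81 and 61. Among annotated origins of cdc25-22, 53 of 152 lay between divergent genes and 65 lay in genes, and in rad3∆ the numbers were 80 and 74 of 199. By limma, 4906 of 12161 windows (40.3%) lay above 0 in cdc25-22 and 4773 (39.3%) in rad3∆, with 4215 shared. A count of windows above 0 depends on the centring, and centring on the 25th percentile moved the median window to 0.17 in cdc25-22 and 0.16 in rad3∆ and gave 8329 and 8306 windows.

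Other gene groups took different places in the replication profile. The windows of tRNA genes averaged 0.16 ± 0.02 in both strains, with 82 of 112 above 0 in cdc25-22 and 81 in rad3∆. Of 7 histone genes, 5 were below 0 in both strains, such as pht1, the gene of histone H2A.Z, with -0.21 ± 0.03 in cdc25-22 and hht3, a gene of histone H3, with -0.21 ± 0.03. The other two, hta1 and htb1, a divergent pair for H2A and H2B, had 0.42 ± 0.00 and 0.34 ± 0.02. The list of histone genes averaged -0.02 and -0.04, and both means were above 0 with centring on the 25th percentile. Of 10 targets of MBF, the transcription factor of G1 and S phase genes, 5 were below 0 in cdc25-22 and 1, the cohesin gene rad21 with 0.19 ± 0.03, was above. The lowest were dut1, which encodes dUTPase, with -0.35 ± 0.04, and ssb1, a subunit of replication protein A, with -0.31 ± 0.02. Their list averaged -0.13 ± 0.01 and -0.09 ± 0.01 (adjusted p of 0.000199 and 0.000251 by fry), and both means were above 0 with centring on the 25th percentile.

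Of 8 checkpoint genes, chk1 (0.35 ± 0.06 in cdc25-22) and rad9 (0.27 ± 0.01), which encodes a subunit of the checkpoint clamp, were above 0, and 5 were below. The window of rad3 lies wholly in the deletion, so its value in rad3∆ measures no replication. That of swi1 overlaps the deletion, so its value in rad3∆ does not measure replication of the whole window. Convergent intergenic regions averaged 0.08 and 0.10, divergent ones 0.04 and 0.06, and tandem ones 0.03 and 0.04 in cdc25-22 and rad3∆. The most AT-rich 5% of windows averaged 0.09 ± 0.03 and 0.16 ± 0.03. The mating-type region had 0.08 ± 0.03 and 0.10 ± 0.04, and the ends of chromosome III next to the ribosomal DNA had 0.12 ± 0.02 and 0.10 ± 0.01. Mitochondrial probes averaged -0.24 ± 0.18 and -0.15 ± 0.20, a spread wider than the difference between the strains.

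The second comparison asked how the loss of rad3 changed the use of origins. Origins that rose in rad3∆ mostly had low log2 ratios in cdc25-22 and lay on chromosomes I and II. Such a ratio is relative to the array median, so it does not show that an origin was silent. Origins could also be called by their height in rad3∆ alone, which favours low values in cdc25-22 among the rises. The rises named here lie towards chromosome ends, where the rad3∆ profile was also higher over broad stretches. Of each named rise, 0.060 to 0.153 lay in the running mean over the surrounding region and 0.126 to 0.166 was local. The largest rise was between SPBC8E4.03 and ecl3 at 4438000 to 4440999 of chromosome II, from -0.07 ± 0.03 to 0.22 ± 0.02 (difference 0.29, SE 0.03, adjusted p = 0.000901 in limma over the called origins alone). Next came an origin between gms2 and miy1 at 324000 to 326999 of chromosome I, from -0.06 ± 0.04 to 0.22 ± 0.07. The origin between utp6, a gene of ribosome assembly, and sid4, a gene of the septation network, at 4359000 to 4361999 of chromosome II went from -0.01 ± 0.04 to 0.23 ± 0.02. That between mug58 and bmt2 at 363000 to 365999 of chromosome I went from 0.06 ± 0.05 to 0.30 ± 0.02, and that between alg6 and qrs1 at 4201000 to 4203999 of chromosome II from 0.05 ± 0.03 to 0.27 ± 0.06. An unannotated origin at 5385000 to 5387999 of chromosome I went from 0.05 ± 0.04 to 0.27 ± 0.03. For these last 5 origins the adjusted p over the list alone was 0.00277 to 0.00734. All 3 rad3∆ replicates lay above all 3 cdc25-22 replicates at each, which the rule for naming them required.

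**Figure D1:**
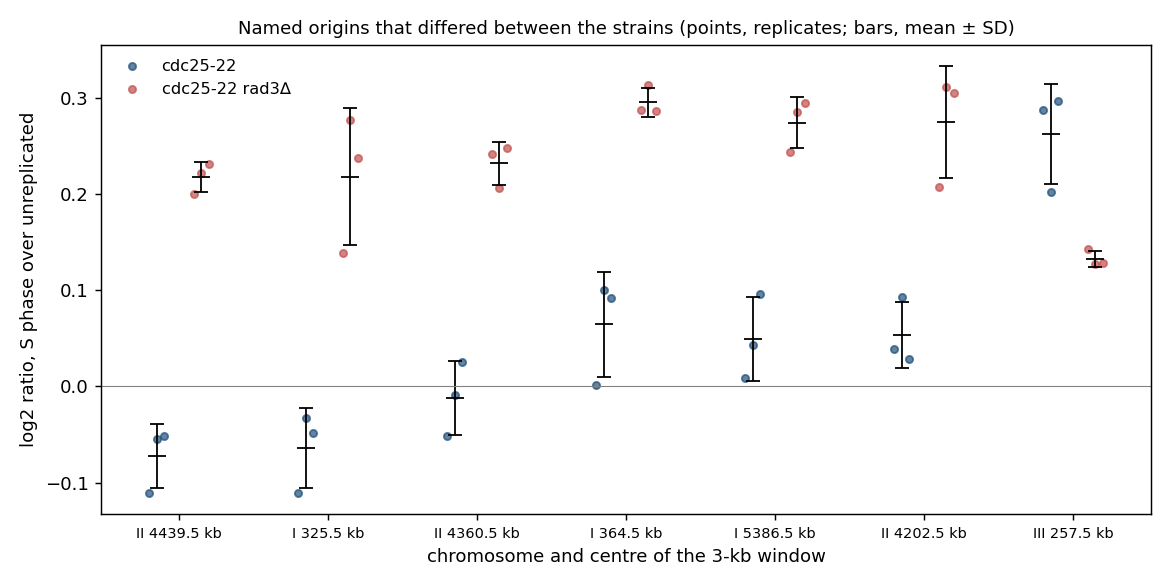
Log2 ratio of S phase over unreplicated DNA (vertical axis) at the 7 named origins that differed between the strains (horizontal axis, chromosome and centre of the 3-kb window); points are replicates and bars the mean ± SD of 3. At the 6 origins on chromosomes I and II the rad3∆ points lie above the cdc25-22 points, and at the origin on III they lie below, as the rule for naming them required.

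Adjusted over the list alone, 32 of the 247 origins called in either strain were higher in rad3∆ and 1 was lower, against 25 and 1 adjusted over all windows. The 32 had a median of 0.10 in cdc25-22 and 0.26 in rad3∆, and 31 of them were called only in rad3∆. An origin joined the 247 by its height in either strain, 71 only in rad3∆ and 11 only in cdc25-22. The counts, the low median in cdc25-22 and the p over the list alone are therefore partly set by this choice. Chromosomes I and II held 17 and 15 of the 32, and chromosome III held 0 although it had 69 of the 247 called origins. Of 28 with annotation, 14 lay between divergent genes. The one that fell lay between SPCC794.16 and SPCC794.06 at 256000 to 258999 of chromosome III, from 0.26 ± 0.05 to 0.13 ± 0.01 (adjusted p = 0.0272 over the list alone and 0.045 over all windows). With the slide as a block its adjusted p over all windows was 0.0606, and without cdc25-22 replicate 1 or 3 or rad3∆ replicate 1 or 3 it was 0.198, 0.133, 0.0926 and 0.109. Without any of the last 3 of these the count of lower origins was 0, and without rad3∆ replicate 2 it was 4. With centring on the mode 73 origins were higher and 0 lower, and the fall on III no longer passed the test (-0.09, adjusted p = 0.256 over all windows). With the slide as a block 38 were higher and 2 lower. The GC correction, which has no values right of the centromere of chromosome I, gave 15 higher, against 30 when that arm alone was left out, and S phase DNA in Alexa 647 only gave 10. Without cdc25-22 replicate 1 the count of higher origins was 9, without cdc25-22 replicate 2 or rad3∆ replicate 3 it was 17 each, and without rad3∆ replicate 1 it was 49. Without cdc25-22 replicate 1, of the 6 named rises only that between SPBC8E4.03 and ecl3 passed over all windows (adjusted p = 0.0491), and the others had 0.0519 to 0.0793. Without cdc25-22 replicate 3 the rise between alg6 and qrs1 did not pass either (0.209, adjusted p = 0.0609).

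Across the 247 called origins the heights of the strains correlated at r = 0.70, and across all windows the profiles did at r = 0.93. At 85 of the 247 (34.4%) the 3 replicates of one strain lay apart from the 3 of the other, 70 with rad3∆ higher and 15 with rad3∆ lower. Chance gives 10% at any given place if replicates are interchangeable. The called origins were kept for their height in either strain, which favours places where the strains differ. They also share shifts over broad regions, so setting their share against 10% is no test. The median difference over called origins was 0.04 on chromosome I, 0.05 on II and -0.03 on III.

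Over whole regions, 717 windows were higher in rad3∆ and 101 lower, with median differences of 0.17 and -0.12. Higher windows made up 87.7% of those that changed, and 99.8% (910 against 2) with centring on the mode and 77.7% (560 against 161) with centring on the 25th percentile. With the slide as a block, the same split as the replicate number, 549 were higher and 17 lower. Without cdc25-22 replicate 1 only 11 windows were higher and 0 lower. Leaving out another replicate gave 233 higher (cdc25-22 replicate 2), 218 (cdc25-22 replicate 3), 302 (rad3∆ replicate 1), 1044 (rad3∆ replicate 2) or 285 (rad3∆ replicate 3), with 3, 3, 8, 387 or 15 lower.

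The subtelomeres of chromosomes I and II averaged -0.20 ± 0.05 in cdc25-22 and -0.05 ± 0.04 in rad3∆. There 136 of 328 windows were higher and 0 lower, whereas 5.9% of all windows were higher, and at the ends of chromosome III 0 of 70 were. All 3 rad3∆ replicates were above all 3 cdc25-22 replicates (exact permutation p = 0.1, the smallest possible), and the differences within slides 1, 2 and 3 were 0.18, 0.15 and 0.12. As a list the subtelomeres did not pass the threshold (fry adjusted p = 0.0901, and 0.125 with the slide as a block), and with centring on the mode they did (0.0472). With centring on the 25th percentile the rad3∆ mean was above 0, at 0.11, and the difference stayed at 0.14.

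Chromosome parts were also averaged, but they were chosen for their values and those at the ends overlap the subtelomeres, so they add no separate evidence. In the last 50 kb of chromosomes I and II the mean was -0.28 ± 0.05 in cdc25-22 and -0.10 ± 0.05 in rad3∆. In the outer 300 kb of the long arm of chromosome II it was -0.19 ± 0.02 and -0.06 ± 0.02, with 156 of 297 windows higher, and in the outer 300 kb of the right arm of chromosome I it was -0.20 ± 0.01 and -0.09 ± 0.01. Early parts went the other way. Chromosome III averaged 0.16 ± 0.02 in cdc25-22 and 0.10 ± 0.01 in rad3∆, and windows within 300 kb of the centromeres of chromosomes I and II averaged 0.12 ± 0.01 and 0.07 ± 0.03. Each of these parts had an exact permutation p of 0.1, the smallest that 3 against 3 can give, and kept its sign within each slide. Falls and rises here are relative to the array median, and the parts were averaged with that centring only. Centring on the mode moved the median difference over windows from -0.008 to 0.029 and left 2 windows lower, so the falls do not show a loss of signal.

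**Figure D2:**
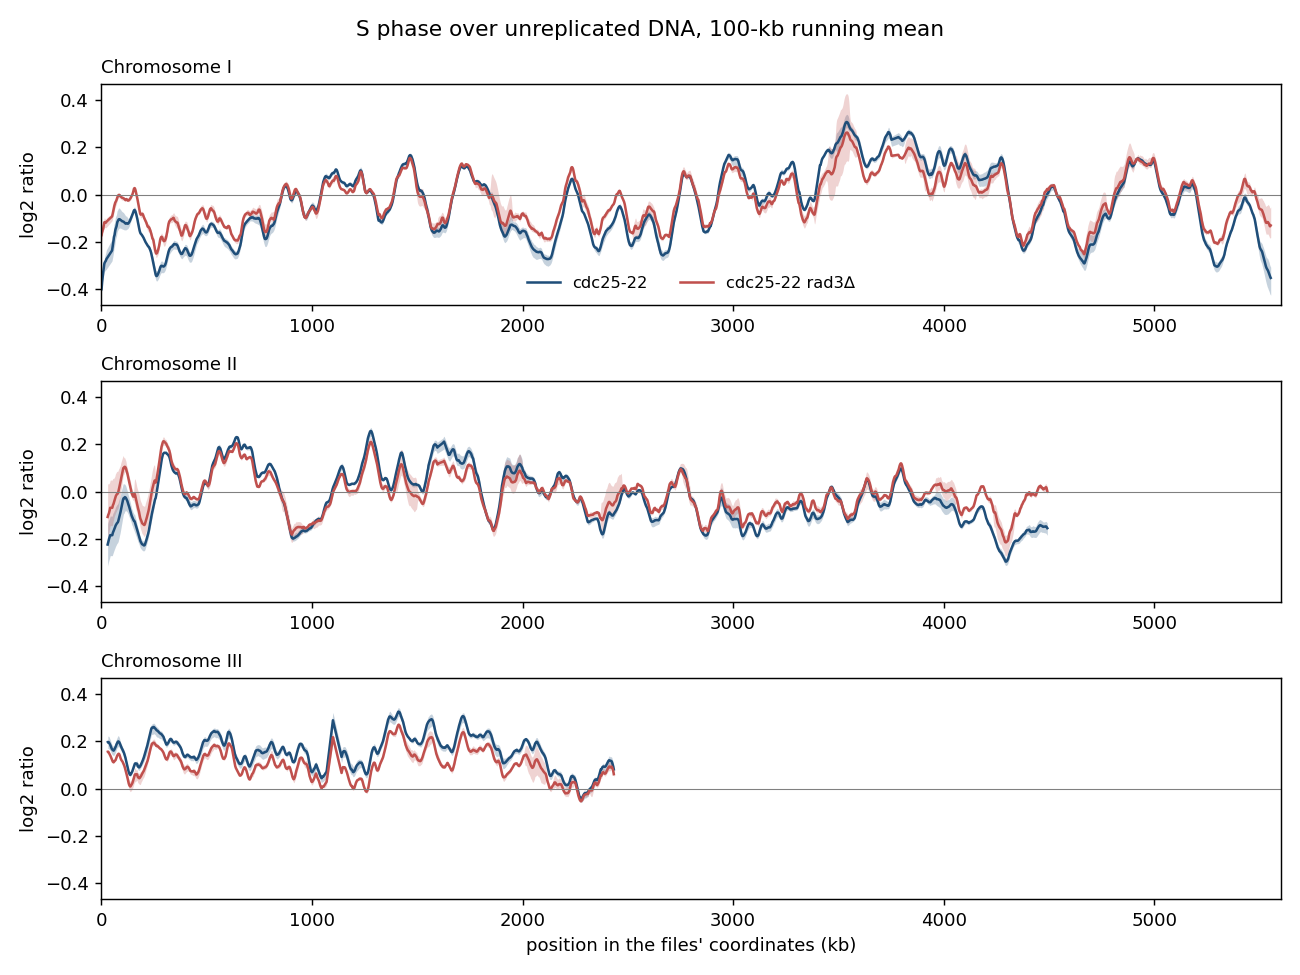
Mean log2 ratio of S phase over unreplicated DNA in a running window of 100 kb (vertical axis) along chromosomes I, II and III (horizontal axis, kb); lines are strain means and shading spans the lowest and highest of 3 replicates. The rad3∆ line lies above the cdc25-22 line near the ends of I and II and below it on most of III and around the centromeres of I and II.

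**Figure D3:**
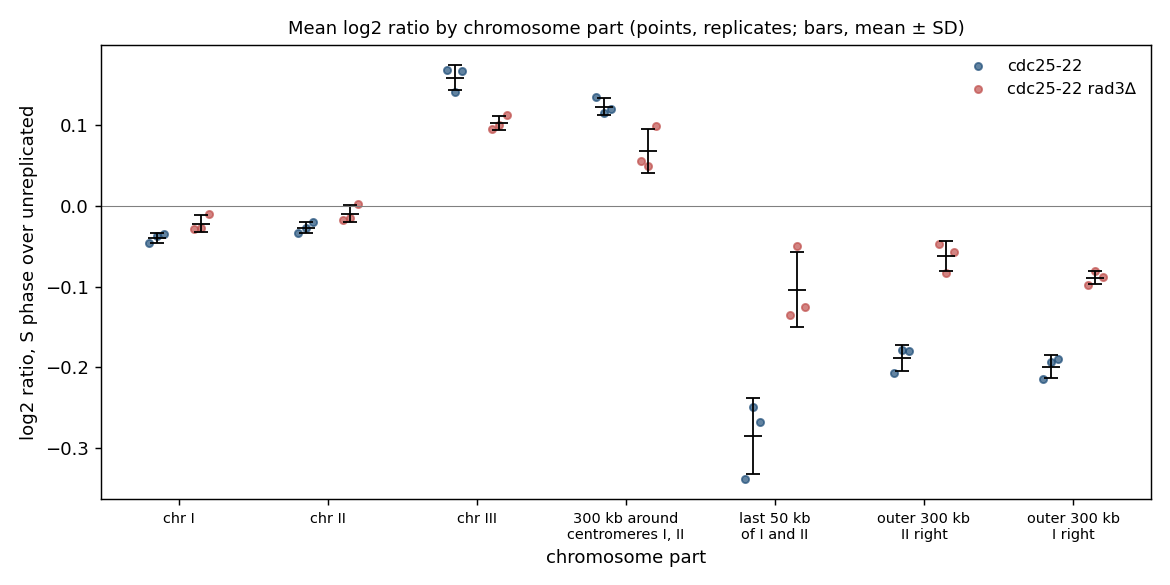
Mean log2 ratio (vertical axis) of each chromosome and of chromosome parts (horizontal axis) per replicate, with the mean ± SD of 3; parts were chosen after the values were seen. Relative to the array median, the last 50 kb of I and II rise from -0.28 to -0.10 and chromosome III falls from 0.16 to 0.10.

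The other lists gave no change that passed the test, and 0 of 15 lists did in all, where 3 (subtelomeres, MBF targets and the ura4 cluster) had an unadjusted fry p under 0.05. The centromeres differed by -0.06 (adjusted p = 0.257), the ura4 cluster by -0.07 (0.203), the most AT-rich windows by 0.07 (0.227), MBF targets by 0.03 (0.203), tRNA genes by 0.002 (0.975), and histone genes by -0.02 (0.566). The 6 checkpoint genes outside the rad3 deletion differed by -0.021 (0.354, in the 1 setting that left the deletion out, chosen after seeing the data). With normexp background correction 5 lists passed, the subtelomeres (0.0139), the ura4 cluster (0.0139), tRNA genes (0.0229), AT-rich windows (0.0291) and centromeres (0.0417). Among MBF targets, adjusted over the list alone, 2 of 10 were higher in rad3∆ and 0 lower, whereas 0 passed over all windows. These were dut1, from -0.35 ± 0.04 to -0.25 ± 0.00, and suc22, the small subunit of ribonucleotide reductase, from 0.02 ± 0.03 to 0.15 ± 0.06, with adjusted p = 0.0237 in limma over the list alone for each. Of the 7 histone genes and these 6 checkpoint genes 0 passed in limma over the list alone, with cds1, the kinase that answers stalled forks, at 0.06 ± 0.02 and -0.01 ± 0.07.

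Measures of the whole profile were taken per replicate. The SD of the profile was 0.204 ± 0.009 in cdc25-22 and 0.195 ± 0.010 in rad3∆ (exact permutation p = 0.2), the 99th percentile was 0.40 ± 0.03 and 0.40 ± 0.05 (p = 1 by the same exact test), and 19.6% ± 1.9 and 18.2% ± 2.0 of windows reached 0.2 (exact p = 0.5). The mean height of called origins was 0.27 ± 0.03 and 0.30 ± 0.03 (exact p = 0.2). Around 133 origins at least 20 kb from the next, the average peak was 15.1 ± 1.7 kb wide at the level midway up in cdc25-22 and 10.6 ± 3.6 kb in rad3∆ (exact permutation p = 0.1, the smallest possible). Within slides the width differed by -3.85, -7.72 and -1.98 kb. The origins were called in either strain, so the average of a strain can take in origins called only in the other. The mean difference of -4.51 kb was -2.52 kb with S phase DNA in Alexa 647 only, -2.50 kb in Alexa 555 only and -3.004 kb with normexp.

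**Figure D4:**
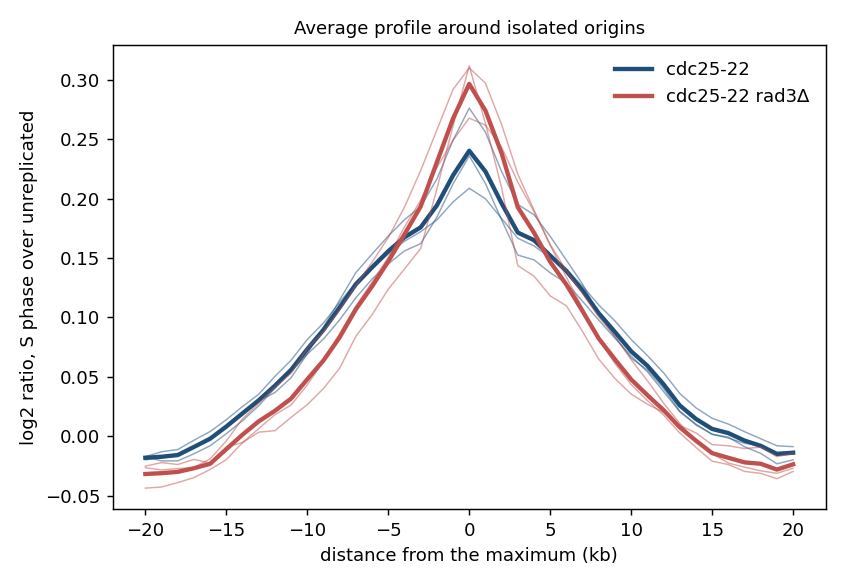
Average log2 ratio of S phase over unreplicated DNA (vertical axis) against the distance from the maximum (horizontal axis, kb) over 133 isolated origins called in either strain; thin lines are replicates and thick lines strain means. The rad3∆ peak is narrower midway up its height, 10.6 kb against 15.1 kb.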

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

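The test of ura4 below, and the use of the planned measures of peak width and of the subtelomeres to weigh explanations, were chosen only after the result was seen. The 7 places here are singled out because the difference between the strains itself passed the test over the called origins. Those origins were kept for their height in either strain, which favours places where the strains differ. That between SPCC794.16 and SPCC794.06 did not pass over all windows with the slide as a block (adjusted p = 0.0606) or with 1 replicate left out in 4 of 6 cases (up to 0.198). Without cdc25-22 replicate 1 only that between SPBC8E4.03 and ecl3 passed over all windows (0.0491), and without cdc25-22 replicate 3 that between alg6 and qrs1 did not (0.0609). The rad3∆ minus cdc25-22 difference was 0.290 between SPBC8E4.03 and ecl3, 0.282 between gms2 and miy1, 0.244 between utp6 and sid4, 0.231 between mug58 and bmt2, 0.225 at the unannotated origin of chromosome I at 5386500, 0.222 between alg6 and qrs1, and -0.130 between SPCC794.16 and SPCC794.06. At the 6 rises 0.060 to 0.153 of the difference lay in the running mean of 100 kb and 0.126 to 0.166 was local. Of the 10 splits of the 6 replicates into 3 and 3, the real one gave 33 changed origins and 818 changed windows, and the highest of the other splits gave 0 of each, so 1 split reached the real count in both cases. For region lists the real split gave 0 and the highest other 1, so all 10 splits gave as many. With 10 splits a share under 0.05 is out of reach.

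The rad3∆ profile was flatter on a broad scale. On the running mean of 100 kb, rad3∆ replicates had a slope of 0.67 ± 0.03 (SD, n = 3) against the cdc25-22 mean, whereas the local profile that remains after removing it had a slope of 1.06 ± 0.06, and cdc25-22 replicates against the mean of their other replicates had 0.998 ± 0.108 and 0.965 ± 0.103. A lower amplitude of the rad3∆ arrays would shrink both scales, but the local slope exceeded the broad slope by at least 0.35 in each rad3∆ replicate, and a GC correction left the broad slope at no more than 0.698, so both explanations are argued against. Forks that had moved further from origins in rad3∆ would widen the peaks. Instead all 3 rad3∆ widths lay below all 3 cdc25-22 widths, the widest below the narrowest by -0.78 kb. The mean difference was -4.51 kb (-6.26 to -2.50 over the alternatives), beside an SD of 3.6 kb across rad3∆ replicates. The width also depends on the height of the apex, and its exact permutation p of 0.1 is the smallest possible. The origins were called in either strain, and of all called origins 71 were called only in rad3∆ and 11 only in cdc25-22. The cdc25-22 average can thus take in places without a called peak of its own. In rad3∆ replicate 2, the narrowest, the apex of 0.31 fell to 0.16 and 0.14 at 3 kb on each side. The peaks were not wider in rad3∆, but on these origins the width cannot decide on longer forks. A role of the rad3 deletion stays open: in the subtelomeres all 3 rad3∆ replicates lay above all 3 cdc25-22 replicates, but the exact permutation p of 0.1 is the smallest possible. The deletion may account for the flattening, as could a different state of the cultures at sampling, which was not tested.

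Probes of ura4 were brighter on the rad3∆ arrays than on the cdc25-22 arrays, in data that the comparisons of ratios do not use. Against the probes 2 to 10 kb away the mean gain was 0.468 log2 units over the 12 channels of the rad3∆ arrays, with a range of 0.09 to 0.90, while on the cdc25-22 arrays the channels ran from -0.39 to 0.62. Averaged per replicate it was 0.75, 0.31 and 0.35 in rad3∆ against 0.18, -0.29 and 0.11 in cdc25-22 (exact permutation p = 0.1, the smallest possible), and within slides it was 0.57, 0.60 and 0.24. The gain reached past the gene, with single probes from 114334 to 117362 of chromosome III gaining up to 0.93. It was uneven, and the probe at 115080 to 115139 within that span changed by -0.03. A second copy of ura4, placed as the marker of the deletion, may be the source of a gain of 0.468, but single channels of the strains overlap, the gain is below the 1 log2 unit that a doubling gives, and the labels name no marker, so the question stays open.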

How the results depend on the processing

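The alternatives chosen after seeing the data were 4, and all others were chosen before: the GC correction with the replicate block, leaving out spike and dip loci and the rad3 deletion, leaving out chromosome I right of the centromere, and keeping replicate 1 of rad3∆ alone, which is then assumed to vary like the cdc25-22 replicates. All 818 changed windows kept their sign in every setting that measured them, and the 6 named rises kept theirs in all settings that gave a value, with adjusted p over all windows of up to 0.0793 for that between alg6 and qrs1. Both sets were chosen for their difference in these replicates, which the settings reuse, so a kept sign is no separate evidence. Which windows pass the threshold depends on the settings and on single replicates, and the cause was not tested unless stated. A value that passed the threshold in neither of 2 settings was compared by its size alone. At least 97.2% of probes were well above background on every array, and with 28 repeated probes that filter was nearly void.

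Windows higher in rad3∆ (717) numbered 195 with normexp, 162 with windows 1 kb wide, 362 with S phase DNA in Alexa 647 only, 146 at an adjusted p under 0.01 (a stricter threshold) and 444 under the GC correction with the replicate block. Leaving out 1 replicate gave 11 to 1044. Windows lower in rad3∆ (101) numbered 4 with normexp, 240 with loess, 2 with centring on the mode, 161 with centring on the 25th percentile, 4 with windows 1 kb wide, 353 with windows 5 kb wide, 8 with Alexa 647 only, 17 with the replicate block and 17 with the slide as a block, which is the same fit, 0 at 0.01, 13 under the GC correction with the block and 272 without spike loci. Leaving out 1 replicate gave 0 to 387. Windows above baseline were 8329 in cdc25-22 and 8306 in rad3∆ with centring on the 25th percentile, which by construction raises every value.

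Origins called in cdc25-22 (176) numbered 307 with centring on the 25th percentile, 267 with Alexa 555 only, 284 with profiles divided by their SD and 24 at a minimum height of 0.4, where rad3∆ had 10. Origins higher in rad3∆ (32) numbered 73 with centring on the mode, 73 with centring on the 25th percentile, 10 with Alexa 647 only, 96 with division by the SD, 15 under the GC correction, 20 under it with the replicate block, 7 at 0.01, 71 at a minimum height of 0.1, 0 at 0.4 and 17 with replicate 1 of rad3∆ alone. Leaving out 1 replicate gave 9 to 49. The single origin lower in rad3∆ became 2 with normexp, with loess, without dim probes, with the replicate or slide block, under the GC correction with the block, and without chromosome I right of the centromere. It became 3 with division by the SD, with merged maxima and without spike loci, 4 at a minimum height of 0.1, 5 with the 25th percentile and 6 with Alexa 555 only. There were 0 with plain background subtraction, the mode, windows 1 kb wide, Alexa 647 only, a threshold of 0.01, a minimum height of 0.4, maxima 10 kb apart and replicate 1 of rad3∆ alone. Leaving out 1 replicate gave 0 to 4.

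The count of changed region lists (0) was 5 with normexp and 1 with centring on the mode. The strain difference in profile SD was 0.0091 with normexp against -0.0093. The difference in the share of windows at 0.2 or more was 0.633 with normexp and 4.18 with the mode, against -1.40 percentage points. The difference in mean origin height was -0.0039 with Alexa 647 only, 0.079 with the mode and 0.28 with division by the SD, which by construction changes the scale and gave 0.058 for the 99th percentile. Signs turned with centring on the 25th percentile for subtelomeres in rad3∆ (0.11), histone genes in cdc25-22 (0.15) and rad3∆ (0.12), MBF targets (0.043 and 0.066), and cdc25-22 at the origins of gms2 (0.11), utp6 (0.16) and ecl3 (0.10). They also turned for histone genes with windows 1 kb wide (0.031 in cdc25-22, 0.039 in rad3∆) and in rad3∆ with the mode (0.010), for mitochondrial probes in rad3∆ with Alexa 647 only (0.37), and for cdc25-22 at the origin of ecl3 with Alexa 555 only (0.0049).

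Replicates of one number shared a slide and an extraction protocol, but their deviations did not pair them over the whole profile. Deviations from the strain means correlated at 0.14, -0.08 and -0.20 for the numbers 1, 2 and 3, and 1 of 3 cdc25-22 replicates correlated best with its own number. The replicate block gave 549 windows higher and 17 lower, and 38 origins higher and 2 lower, and the fall between SPCC794.16 and SPCC794.06 then had an adjusted p of 0.0606 over all windows (0.0203 to 0.256 over all alternatives). Over all windows dut1 had an adjusted p of 0.0363 to 0.632 and suc22 of 0.009 to 0.436. Of the remaining values of single places and lists, 2729 stayed on their side of the threshold or within their spread (1899 above 0 and 830 below), 61 no longer passed (34 and 27), 84 newly passed (61 and 23) and 125 moved by more than their spread (75 and 50).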

Other observations

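The sequence at called origins was tested for both strains together. Over the 210 annotated origins called in either strain the AT content was 67.3% ± 1.8 (SD across origins), against 63.9% ± 2.4 across all annotated windows. Of the origins 61.4% were centred between genes, against 21.8% of windows, and 39.5% lay between divergent genes, against 10.2%. That origins lie in AT-rich intergenic DNA was written as a hypothesis before its test, and 10000 circular shifts of the profile gave a p of 0.0001 for both properties, the smallest they can give. These origins were called without the GC correction, and those called with it were not tested. A trend of the ratio with base composition was therefore not separated from this result.

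Sharp spikes and dips stood at 27 loci where at least 1 replicate lay over 0.5 from the median of the 6, and at 8 of these more than 1 replicate did. This limit and the tests of GC content and of the rad3 deletion at these loci were chosen only after the values were seen. All 12 spikes were furthest out in rad3∆ replicate 3 and all 15 dips in rad3∆ replicate 2. Spikes lay in gar2 and fib1, genes of nucleolar proteins, and in rps1002, a ribosomal protein gene, where replicate 3 had 1.104, 1.098 and 1.203. Dips lay in pabp, the gene of the poly(A)-binding protein, in tdh1, a glyceraldehyde-3-phosphate dehydrogenase gene, in fas2, a fatty acid synthase gene, and in ssa2, a chaperone gene, where replicate 2 had -1.09, -0.85, -0.97 and -0.55. Genes of a nucleolar and a ribosomal protein, gar1 and rpp201, also held dips, with -0.47 and -0.49 in replicate 2. All these genes are examples, and a link to a class of genes was not tested.

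A trend of GC content is argued against at the 20 loci with GC content, where the correction left 0.973 of the median deviation (0.872 to 1.041 per locus) and all 20 past the limit. It stays open at the 7 loci where the reference gives no GC content. In replicate 3 the unreplicated channel was lower than the cdc25-22 mean at all 12 spikes (median -1.03), and than every cdc25-22 replicate at 11 of them, while the S phase channel changed by 0.11. Of the change 0.877 lay in the unreplicated channel. At the 15 dips the S phase channel of replicate 2 was lower at all (median -0.95), and its unreplicated channel was lower at 14 (median -0.20). DNA of these loci lost from 1 of the 2 extracts of a replicate could give the spikes and dips, but replicate 2 was low by over 0.5 in both channels at 11 of the 12 spikes. Loss from 1 extract and unequal loss from both therefore cannot be told apart. The rad3 deletion stays open too: all 3 rad3∆ replicates lay on one side of all 3 cdc25-22 replicates at 1 of 27 loci, but the loci were chosen for single replicates, and the furthest was a rad3∆ replicate at all 27. At some spikes a cdc25-22 replicate was also past the limit, such as in lsd90 (replicate 3, 1.198) and deb1 (replicate 2, 0.861). A spike at such loci thus also arose with rad3 present. The origin named in fib1 is one of the 27 loci.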
